A study of Tetrahymena thermophila with 2 samples.

How the data were processed

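RNA was sequenced from 2 cultures of the ciliate Tetrahymena thermophila, the wild-type strain CU428 (WT) and a strain in which a SMYD gene had been knocked out (SMYD-KO), with 1 library per genotype. Per the labels' protocols, each culture was 10 ml of a rich peptone-based medium (SPP) harvested in log phase at 200000 cells per ml, the knockout was made by particle bombardment, and libraries were made from total RNA with the Illumina TruSeq protocol. The genotype label of each library gave its group.

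The deposited files are RSEM tables with 1 row per gene. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM 1.2.7 were used; the genome build, the annotation, read length and strand setting are not given in the sources used here. Each file holds expected counts, TPM and FPKM as deposited by the authors. The expected count is RSEM's estimate of the reads from a gene, with reads that align to several genes divided between them, and is not normalized. TPM in the deposited files is a gene's abundance over its effective length, scaled to the same total in each library, and FPKM in the deposited files is scaled to gene length and mapped reads. Both are relative to everything else in the same library, so a change in a few very abundant genes moves the values of all others. The deposited gene length was the same as the whole gene span, introns included, in a RefSeq gene table of assembly JCVI-TTA1-2.2 for 26995 of 26996 genes. Values per kilobase are therefore divided by a length that includes introns. Whether reads from introns or across splice junctions entered the counts equally in both libraries was not tested. Of the longer genes, the median difference between length and effective length was 109.27 bases in WT and 119.11 bases in SMYD-KO. RSEM thus used different effective lengths for the same gene in the 2 libraries.

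All 26996 gene identifiers were found in that gene table, but it gives only the locus tag as symbol for every one, and the files pair no identifier with a gene name or product. The 29 gene lists fixed before the data were examined (metabolic pathways, ribosomal proteins, chaperones, histones, cilia, conjugation genes and others) were defined by product names, and so could not be tested. The scan of product families was void for the same reason, and the knocked-out gene could not be located among the identifiers, so its level was not used to check the labels. The rule for genes named in the text was also fixed beforehand. Its fallback for files without product names was applied: 2 genes at each end, ranked by the bound of the 95% counting interval nearest to no change, among genes with a mean of at least 100 TMM-scaled counts.

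Expected counts were rounded to whole numbers. Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.889 for WT and 1.12 for SMYD-KO. The log2 ratio of a gene is SMYD-KO over WT after adding 0.5 to each count. Genes with a summed count of at least 20 over both libraries were compared, and genes beyond 2-fold (ratio above 2 or below 0.5) were counted. With 1 library per group there is no estimate of the variation between cultures, so no test was run and no p-value is given; all counts of genes are counts by size in these 2 libraries. Intervals are 95% Clopper-Pearson intervals of a gene's share of counts in SMYD-KO, turned into a ratio (scipy 1.17.1, Python 3.11.15). A count of 0 allows up to 3 counts. Intervals and floors cover counting error only, neither the variation between cultures nor the uncertainty in dividing shared reads. Medians of gene classes were set against 10000 random lists (or 1000 for inner classes) of the same size, as a description of these libraries. The lists were matched in 20 bins on mean TMM-scaled count, which is not divided by length.

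The list step was tried on random lists of genes with their measured ratios, not on simulated counts. The ratio and interval steps were tested on counts simulated without variation between cultures, from the means and depths of these libraries, for 18214 genes. Of these, 200 were changed by known folds, all drawn from genes with a mean of at least 100 counts. The most abundant genes were also lowered. Of the unchanged genes 0.55% came out beyond 2-fold from counting alone, and the interval held the true ratio for 95.7% of genes. Of the 200, all changed by log2 2 or more were found beyond 2-fold in the right direction. At that depth so large a change could hardly fail to pass, so the result says nothing about detection at lower counts.

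Alternatives fixed beforehand were DESeq2 1.42.0 size factors, total counts, deposited TPM or FPKM with 0.1 added, no count filter, a summed count of at least 200, 5 counts added, an interval wholly beyond 2-fold, and genes with whole expected counts (within 0.01) only. The rule behind the submitters' own gene counts, and totals without the 100 most abundant genes, were added after seeing the data. Pathway enrichment was not analysed here. The gene table served only for the order and spacing of genes in the closing section; its coordinates are not printed, since the build behind the files is not given.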

Results

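Expression of 26996 Tetrahymena thermophila genes was measured in 1 wild-type (WT, strain CU428) and 1 SMYD knockout (SMYD-KO) library from cells growing in log phase. Tetrahymena is a single-celled ciliate with a silent germline nucleus and a transcribed somatic nucleus, and SMYD proteins are methyltransferases that carry a SET and a MYND domain. The comparison addresses the part that SMYD1 plays in gene transcription. The libraries had nearly equal totals, with 20767244 expected counts in WT and 20762677 in SMYD-KO. With 1 library per genotype, no difference below has a replicate check. The files identify genes only by locus tag, so the knocked-out gene could not be picked out and its level was not examined.

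Slightly more genes were detected in SMYD-KO, the library in which a typical gene also received more of the counts (TMM factors of 0.889 for WT and 1.12 for SMYD-KO). At least 1 count was assigned to 22683 genes in SMYD-KO and to 22229 in WT, and 3550 genes had no count in either library. Genes at a TPM of 1 or more numbered 16398 in SMYD-KO and 15399 in WT, and the median TPM over all genes was 2.32 against 1.71. Among genes with a summed count of at least 20, 15 had no count in WT and 5 had no count in SMYD-KO. The 15 genes without a WT count had 20 to 84 counts in SMYD-KO, and the highest of them was at least 22.2-fold higher there, taking the floor of 3 counts per library for the zero. The 5 genes without a SMYD-KO count had 20 to 160 counts in WT, the highest being at least 67.4-fold lower in SMYD-KO. All but 2 of the 15 had whole expected counts in both libraries, against 1 of the 5, so the counts of most of the latter rest in part on reads shared with other loci. Of the 18363 genes with a summed count of at least 20, 5780 had whole counts, so shared reads were common. A count of 0 at these depths allows a level of up to 0.144 CPM.

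The most abundant transcripts took a smaller share of the SMYD-KO library. The 5 genes with the highest TPM in WT held 8.88% of its counts, and those 5 genes held 3.27% of the counts in SMYD-KO; 4 of them were over 2-fold lower after TMM scaling. The 5 genes with the highest TPM in SMYD-KO held 4.25% of its counts and 4.71% of the WT counts, and 2 genes were in both sets of 5. The 100 genes with the highest mean TPM held 30.2% of the counts in WT and 22.5% in SMYD-KO. After TMM scaling, 18 of these 100 genes were over 2-fold lower, 10 over 2-fold higher and 72 within 2-fold, with a median log2 ratio of -0.49. On the total-count scale every log2 ratio is 0.34 higher, so the median loss of share was smaller. Part of the lower share came from 1 gene, described below, which fell from 3.40% of the WT counts to 0.0896% of the SMYD-KO counts.

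The gene that was most abundant in WT was among those furthest below WT in SMYD-KO. TTHERM_00655890, with a gene span of 915 bases, had 707069 counts in WT, 3.40% of the library and first in rank by TPM (52474). In SMYD-KO it had 18598 counts and ranked 109th, which made it 48.1-fold lower after TMM scaling (95% counting interval 47.4 to 48.8). Its expected counts were not whole in both libraries, so RSEM divided some reads between loci, and its value is uncertain if near-identical copies exist. The fraction does not tell how many reads were divided. Genes with such counts held 96.6% of the WT counts and 96.1% of the SMYD-KO counts, so this is common among abundant genes. TTHERM_00361660, with a span of 2445 bases, had 1431 counts in WT and 20 in SMYD-KO, all whole, and was 88.3-fold lower (58.3 to 149). At the other end, TTHERM_00971960, with a span of 1215 bases, had 17 counts in WT and 3781 in SMYD-KO and was 171-fold higher (110 to 302). Its rank by TPM was 15676th in WT and 739th in SMYD-KO, and it too shared some reads with other loci. TTHERM_00644640, with a span of 618 bases, had 3 counts in WT and 850 in SMYD-KO, a ratio of 192 (76.4 to 1089) that rests on very few WT counts.

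**Figure D1:**
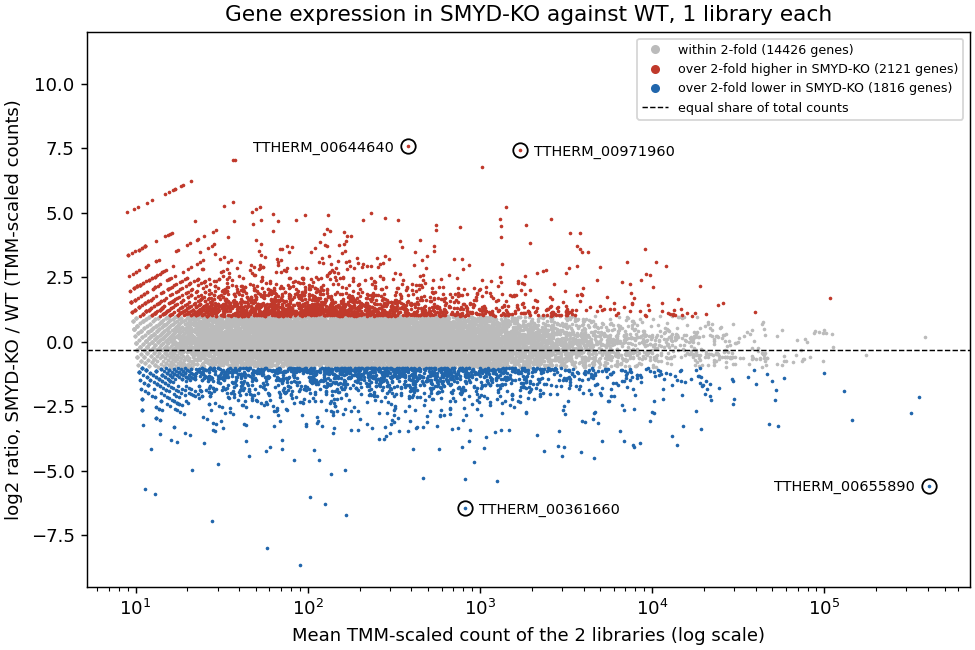
Log2 ratio of TMM-scaled counts (SMYD-KO over WT) against the mean TMM-scaled count on a log axis, 1 point per gene, for 18363 genes in 1 library per genotype; circles mark the 4 genes named in the text. Of the genes, 2121 (red) lie over 2-fold higher and 1816 (blue) over 2-fold lower in SMYD-KO, and the dashed line, at a log2 ratio of -0.34, is where a gene has an equal share of both libraries' total counts.

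After TMM scaling, which by its design places the typical gene near no change, most genes lay within 2-fold and the others lay on both sides in similar numbers. Of 18363 genes with a summed count of at least 20, 14426 (78.6%) were within 2-fold after TMM scaling, 2121 (11.6%) were over 2-fold higher in SMYD-KO and 1816 (9.89%) over 2-fold lower. Over 4-fold, 475 genes were higher and 389 lower, and over 16-fold 62 were higher and 39 lower. The 10th and 90th percentiles of the log2 ratio were -0.996 and 1.08. The counting interval lay wholly beyond 2-fold for 938 higher and 1038 lower genes, beyond 4-fold for 210 and 209, and beyond 16-fold for 17 and 18, so the excess of higher genes did not hold under this stricter rule. How far these numbers exceed the variation between cultures of one genotype cannot be judged from 1 library each.

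The balance between higher and lower genes depended on the scale. On the total-count scale the median log2 ratio of the same 18363 genes was 0.34, and 3681 genes were over 2-fold higher and 1035 lower, so that 78.1% of the genes beyond 2-fold were higher, against 53.9% with TMM. The shift of 0.34 between these scales applies to every gene. The deposited TPM and FPKM, which are relative to the library total, gave 79.4% and 78.6%. The submitters' series text reports 21461 genes, 4841 (23%) of them up and 1507 (7%) down. The same 3 numbers came from the deposited FPKM values with no rescaling when genes with an FPKM above 0 in both libraries were kept and ratios of exactly 2 or 0.5 were counted as changed. Of those 4841 genes, 2106 were also over 2-fold higher after TMM scaling, 1697 were not although they had enough counts, and 1038 had a summed count under 20. Of the 1507 genes, 1030 were also over 2-fold lower after TMM scaling and 477 had a summed count under 20. A further 786 genes were over 2-fold lower only with TMM, and 15 were over 2-fold higher only with TMM. Both numbers include any genes with an FPKM of 0 in 1 library.

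**Figure D2:**
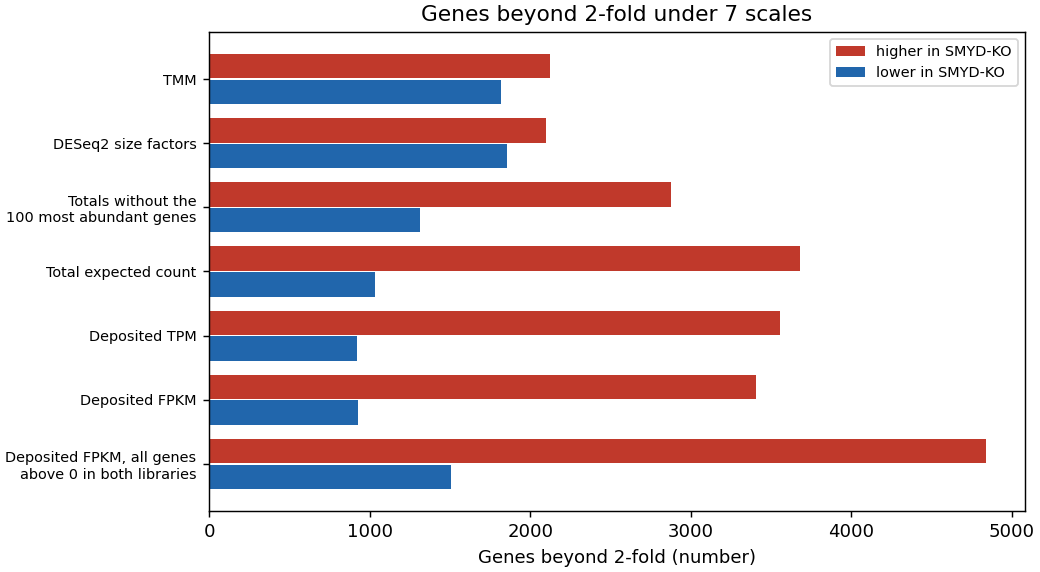
Number of genes beyond 2-fold, higher (red) and lower (blue) in SMYD-KO, under 7 ways of scaling the same 2 libraries. The upper 6 pairs of bars cover the same 18363 genes and the last pair the 21461 genes with an FPKM above 0 in both libraries, with ratios of exactly 2 included; higher genes number 2121 with TMM and 4841 in the last pair.

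Genes of low expression tended to have higher ratios than genes of high expression. With genes ranked by their mean TMM-scaled count and cut into 10 equal classes, the median log2 ratio was 0.17 in the lowest class and -0.19 in the highest. On the total-count scale the same medians were 0.51 and 0.15, both above 0, so the sign for abundant genes holds only relative to the typical gene. In the lowest class, 391 of 1837 genes were over 2-fold higher and 246 over 2-fold lower; in the highest class, 141 of 1837 were higher and 268 lower. Ratios in the lowest class rest on a median of 15.6 counts per library.

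The longest genes had lower ratios than shorter genes of like read count. In 10 equal classes by span, the class of longest genes (5388 to 31898 bases) had a median log2 ratio of -0.19. This was below all 10000 random lists matched on mean TMM-scaled count, whose central 95% ran from -0.05 to 0.03. That count is not divided by length, so the lists do not match the level per base. Whether the trend with length is separate from that level was not tested. In this class 118 of 1837 genes were over 2-fold higher and 171 over 2-fold lower. The next longest class had a median of -0.11, below all of its 1000 matched lists. The class of shortest genes (174 to 665 bases) had a median of 0.07, inside the central 95% of its matched lists (0.0045 to 0.08). Classes 2, 3, 5, 6 and 7, counted from the shortest, lay above theirs, with medians of 0.04 to 0.08; class 3, for example, had a median of 0.08 against an upper bound of 0.04. On the total-count scale the longest and shortest classes had medians of 0.15 and 0.41, both above 0, so the sign for the longest genes holds only relative to the typical gene. The effective lengths that RSEM used also differed between the libraries, with offsets from gene length of 109.27 bases in WT and 119.11 bases in SMYD-KO.

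**Figure D3:**
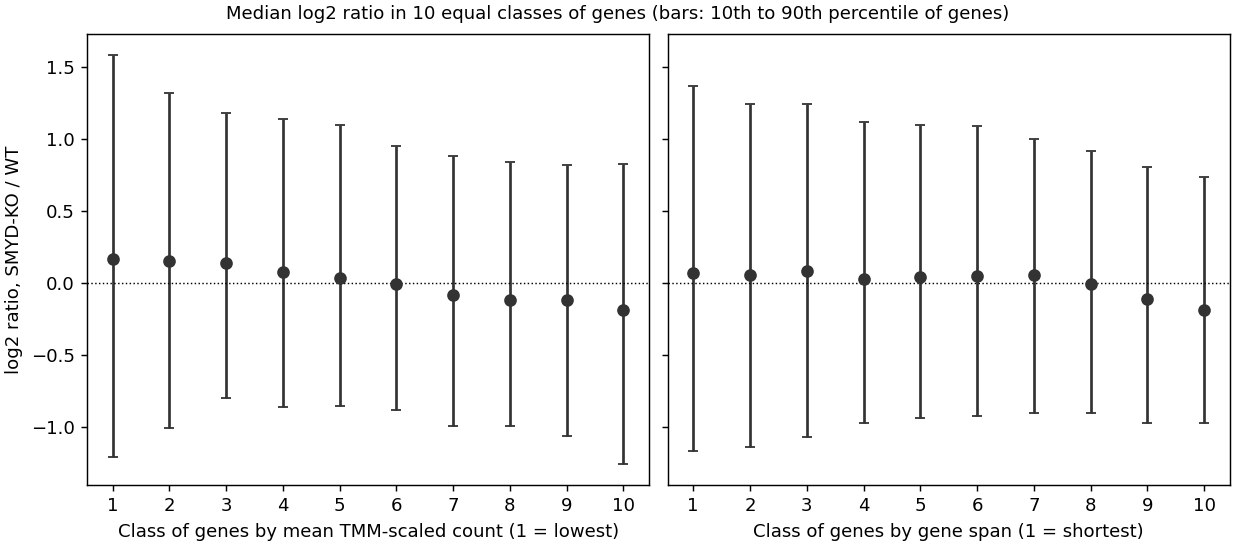
Median log2 ratio (SMYD-KO over WT, TMM-scaled counts; points) with the 10th to 90th percentile of genes (bars) in 10 equal classes of 18363 genes by mean expression (left) and by gene span in bases (right). The medians go from 0.17 in the least expressed class to -0.19 in the most expressed, and from 0.07 in the shortest class to -0.19 in the longest; bars show the spread over genes, not an error between replicates.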

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

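The FPKM rule of the submitters' gene counts and the totals without the 100 most abundant genes were added after seeing the data; the other settings were fixed before the data were examined. The counts of genes beyond 2-fold (2121 higher, 1816 lower) stayed within 1.5 times with DESeq2 size factors (2100 and 1853) and with 5 counts added (1754 and 1704). They moved further on the scales relative to the library total: 3681 higher and 1035 lower with total counts, 3555 and 922 with deposited TPM, 3407 and 926 with deposited FPKM, and 4841 higher (1507 lower) with the FPKM rule. Totals without the 100 most abundant genes gave 2879 and 1311. Total counts, with or without those 100 genes, differ from TMM by a shift common to all genes, which moves higher and lower counts in opposite directions. TPM and FPKM also differ in pseudocount and effective length, and the FPKM rule in the genes kept and in counting ties. Settings that change which genes are counted gave 3829 and 3171 without a count filter, 1048 and 1153 at a summed count of at least 200, 854 and 696 among 5780 genes with whole counts, and 938 and 1038 for intervals wholly beyond 2-fold. Higher genes outnumbered lower genes in all of these except the filter of 200 and the interval rule. The 4 named genes were chosen as extremes of this ratio, so none of the 5 settings run for each could have reversed their direction. Their log2 ratios were 7.09 to 7.76 for TTHERM_00971960, 6.40 to 7.93 for TTHERM_00644640, -6.47 to -5.86 for TTHERM_00361660 and -5.60 to -5.22 for TTHERM_00655890. The medians of the gene lists fixed beforehand have no values under any setting, because the lists could not be formed. No paired analysis was possible because each genotype has 1 library, and leaving out a library leaves no comparison. Depth limits ratios of weakly expressed genes: 4767 genes had no count in WT and 4313 in SMYD-KO.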

Other observations

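The tests in this part were chosen after the patterns were seen, and all but 1 (pairs with whole counts) after the values they measure had been seen in part or the scaffold had been singled out. Genes that lie next to each other had weakly correlated ratios, more alike than in shuffled orders. Across 17883 pairs of adjacent measured genes, ordered by the gene table, the Spearman rank correlation of their log2 ratios was 0.12, against a central 95% of -0.01 to 0.02 in 1000 shuffles within expression bins; genes are not independent replicates. The rank correlation was 0.03 for genes 2 places apart and 0.01 for genes 5 places apart. Runs of 3 or more consecutive measured genes that were all over 2-fold higher numbered 62, against a median of 24 and a highest value of 39 in the shuffles. Runs of genes that were all over 2-fold lower numbered 56, against a median of 15 and a highest value of 28.

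The longest run in each direction held 6 genes. In the lower run, the 6 genes had similar spans of 4036 to 4716 bases, 102 to 1457 counts each in WT and 0 to 304 in SMYD-KO, 3421 against 509 in all, and 5 of the 6 shared reads with other loci. In the higher run, the 6 genes had spans of 1080 to 2879 bases, 12 to 65 counts each in WT and 134 to 502 in SMYD-KO, 278 against 1998 in all, and 3 of the 6 shared reads. Of the 18363 genes compared, 5780 had whole counts, so most genes shared some reads. Unmeasured genes lay within both runs, 1 in the lower and 4 in the higher. Both runs were chosen after their values were seen.

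Reads divided between near-identical neighbours were not the whole cause of this similarity, since the rank correlation was 0.16 among 1985 adjacent pairs in which both genes had whole counts, above a shuffled central 95% of -0.04 to 0.04. When genes without whole counts were dropped before neighbours were paired, it was 0.06. Reads running on between close genes were not the whole cause either: the rank correlation was 0.098 among 10805 pairs more than 1000 bases apart (shuffled -0.02 to 0.02), and 0.15 among 7078 closer pairs. Each of these read effects was tested with the other still present, so the test cannot say whether both together account for the similarity. Among what else stays open, untested here, is regulation of neighbouring genes together, including tandem copies of a gene under the same control.

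The excess of higher genes on the deposited scales has several possible sources. Counting noise in weakly expressed genes is not enough, because at a summed count of at least 200 there were still 3.06 higher genes per lower gene on the total-count scale (1953 against 638). The smaller share of the 100 most abundant genes may account for part of it: with those genes left out of the totals, the median log2 ratio of the other genes was 0.196 instead of 0.34. A general rise of most transcripts in SMYD-KO cells cannot be told apart from a smaller share of abundant transcripts, because the shift of 0.338 that TMM removes has no outside reference such as spiked-in RNA. The knockout itself, another difference between the 2 cultures and a difference in library making are confounded in this design.

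One of the 120 assembly scaffolds with at least 50 measured genes stood low in SMYD-KO. Relative to all genes, its 103 genes had a median log2 ratio of -0.46, and 70 of them lay below 0, 23 over 2-fold lower and 4 over 2-fold higher. Because it was picked as the lowest of 120, it was set against the lowest scaffold of each shuffle. Some scaffold had a median as low in 14 of 1000 shuffles of blocks of 5 neighbouring genes, and in 3 of 1000 shuffles within classes of expression and length, which argues against chance among scaffolds and against the expression and length of its genes; the latter shuffle moved single genes and so ignored the similarity of neighbours. Whether the scaffolds as a set stood apart depended on the shuffle: the SD of their 120 medians was 0.112, inside the central 95% of the block shuffles (0.0855 to 0.114) and above that of shuffles within expression bins (0.0805 to 0.106). In the latter, a second-lowest median as low as that observed (-0.31) appeared in 27 of 1000 shuffles and a median as high as the highest (0.34) in 107. Fewer copies of that chromosome in the knockout strain is a candidate explanation, as a hypothesis only. It stays open: all 6 equal parts of the scaffold had medians below 0, but the highest was -0.202 with a bootstrap interval from -0.75 to 0.22. Only the part with the lowest median (-0.64) had an interval wholly below 0 (-1.22 to -0.27), and every other interval reached above 0. The intervals are too wide to show a shift along the whole scaffold, and DNA was not measured in the files used here.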
